A study of Gossypium hirsutum with 3 samples.

How the data were processed

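Leaves of cotton seedlings were sampled once per condition, and 1 degradome library was made for each of the control, 4 h salt and 5 d salt groups, as the sample labels name them. Per the labels' protocols, polyadenylated RNA from 200 μg of total RNA was ligated at its free 5′ end to an adapter with a recognition site of MmeI, an enzyme that cuts at a fixed distance and so leaves short tags. The ligated RNA was copied, amplified, cut with MmeI and amplified again before Illumina sequencing. No molecular identifiers are described, so reads copied from one molecule cannot be told from reads of separate molecules.

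The deposited sample files give the length, the sequence and the count of each distinct tag, as raw counts of reads without normalization. The series design text gives 864720, 1217757 and 1171577 clean reads. The first and the last equal the number of distinct tags in the control and 5 d files, while the 4 h file holds 7017065 distinct tags. Its longest tag has 24 nt, against 44 in the control and 42 at 5 d. The 4 h file may therefore have been filtered or processed in another way, which bears on every comparison with 4 h. The totals used here are the sums of counts, 22653372 reads for the control, 30649472 for 4 h and 20685800 for 5 d. Scaled to the total, 1 read is 0.0441, 0.0326 and 0.0483 reads per 1000000 (RPM), and the floor of 3 counts is 0.132, 0.0979 and 0.145 RPM. The table deposited with the series lists, for each transcript, positions with reads and a score, the authors' normalised value. The ratio of reads to that score gives a scaling total of 22653372, equal to the total of the control file; the table names no sample, was not assigned to one, and its values are given as the authors'. All 39314 coding lengths are multiples of 3, so the sequences hold no untranslated regions. The aligner, the genome build and the filters behind the table are not given in the sources used here. The reference table of 99454 genes matched 0 of the 39314 identifiers, so no gene names are given, and no genome sequence was used here.

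The design had foreseen a table with miRNA, category and values per library. The table has none of these, so cleavage sites were defined on the tags. Tags were joined by their first 18 nt, called an end. An end counted as a site of a family when its first 9 nt were the exact complement of nucleotides 2 to 10 of the miRNA, which places the cut opposite nucleotides 10 and 11. The 37 sequences were written from general knowledge of conserved plant miRNAs before any tag was searched; miR165 and miR166 share 1 word, which leaves 36 distinct words, and families whose sequence was not certain were left out. The background is the count of the same word at the 8 next registers of the tag. A site is thus a sequence match, not an alignment to a transcript: an end can come from several near-identical transcripts, its gene is uncertain, and a miRNA target with a mismatch in this stretch is missed.

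After the first search had been read, 23 other word forms known from target mismatches were tried. They were chosen after seeing the data, are not part of the reported site set, and are given together in the closing section. The factor of 3 over the highest shifted register was also set after the counts had been seen.

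Ratios of RPM were computed for ends with at least 20 reads over the 2 libraries compared, with exact conditional binomial (Clopper-Pearson) 95% intervals. No test between conditions was made. The overlap of independent lists is not given, because it needs all possible sites and the tags show only those seen in a library. The named ends are those with the interval bound farthest from 1 among ends whose whole interval lies above 2 or below 0.5, up to 10 in each direction, of which the text gives the first few; the rule of 1 site per transcript could not be applied. The most abundant end of each family and the 5 ends with most reads in each library were also listed. For 12 lists of families fixed in advance, the median log2 ratio with a pseudocount of 0.5 RPM was set against 10000 random lists of ends matched in 40 classes of mean abundance. Lists under 3 ends gave no value.

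Among tags with at least 5 reads, the modal copy numbers of the control and 5 d libraries are 53 and 16, so intervals were also computed after dividing reads by that number, and by 1 in the 4 h library. Each 4 h read stayed 1 molecule also where the copies per molecule were doubled. The intervals in molecules thus make no allowance for copies made by PCR at 4 h. This gives an approximate count of molecules and was chosen after seeing the data, as were leaving out the 2 dominant ends, alone or together with it, doubling the copies per molecule, taking the lowest or the highest hump from 5 to 60 reads (27 or 53 in the control, 16 or 33 at 5 d) as 1 molecule, splitting the miR164 register, a word of 10 nt and the word forms tried later. Alternatives fixed before the data were examined were other denominators, other minimum counts, tags within 1 nt, thinning to the shallowest library, other pseudocounts, and counting each pair of miRNA and target. On simulated counts for 20000 ends of the comparison of 4 h with control, intervals covered the true ratio for 96.4% of ends, and 59.0% of 200 ends changed 4-fold and 0% of unchanged ends passed the 2-fold bound. For 5 d against control, 52.0% of changed and 0.0101% of unchanged ends passed, and for 5 d against 4 h, 40.5% and 0.0101%. The simulation has no PCR copies. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.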

Results

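Degradome tags were collected from leaves of upland cotton (Gossypium hirsutum, cultivar SN-011) to compare the cleavage of miRNA targets with and without salt. A degradome library captures polyadenylated RNA with an uncapped 5′ end, so each tag starts where an RNA was cut or stopped decaying, and a miRNA-guided cut leaves an end opposite nucleotides 10 and 11 of the miRNA. There was 1 library for each of 3 conditions: a non-saline control, 150 mM NaCl for 4 h, and 150 mM NaCl for 5 d, reached in steps of 50 mM every 12 h. No difference between conditions has a replicate check. The labels give no sampling time for the control, so plant age and time of day are not separated from salt in comparisons with it. All intervals are exact 95% intervals that cover counting error only, since copies made by PCR are not independent molecules.

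The control library held 22653372 reads in 864720 distinct tags, the 4 h library 30649472 reads in 7017065 distinct tags, and the 5 d library 20685800 reads in 1171577 distinct tags. Tags of 20 and 21 nt made up 99.1% of control reads (interval 99.07 to 99.08%), 99.5% of 4 h reads (99.45 to 99.46%) and 97.4% of 5 d reads (97.41 to 97.42%). Tags that end in a run of 8 A made up 0.0985% of reads in the control (0.0972 to 0.0998%), 0.0561% at 4 h (0.0553 to 0.0570%) and 0.691% at 5 d (0.687 to 0.694%).

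A pair of neighbouring 5′ ends led all 3 libraries. The ends AGAATGCATTGGATGGAT and GAATGCATTGGATGGATG, 1 nt apart, together took 5.55% of control reads (5.54 to 5.56%), 53.8% of 4 h reads (53.80 to 53.84%) and 5.21% of 5 d reads (5.20 to 5.22%). The 10 most abundant ends took 5.98% of control reads, 54.9% of 4 h reads and 5.72% of 5 d reads. Reads per 1000000 reads of the library (RPM) for every other end of the 4 h library are therefore lower by construction, and values without the 2 ends are given beside them below. Leaving the 2 ends out multiplied each ratio of 4 h to control by 2.05, a shift of 1.03 on the log2 scale.

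The libraries also differed in how often each tag was copied. In the control, 54.6% of distinct tags had 1 read, 20489 tags had 2 to 9 reads and 357470 tags had at least 20 reads, with the most frequent copy number among tags of at least 5 reads at 53, called the modal copy number below. In the 5 d library, 40.3% of tags had 1 read, 416599 tags had at least 20 reads, and the modal copy number was 16. Between 5 and 60 reads the control had another hump with fewer tags at 27 reads and the 5 d library one at 33. In the 4 h library 73.4% of tags had 1 read and the number of tags fell away from 1 read on, with 38278 tags at 20 reads or more. The 4 h file also has no tag over 24 nt, where the others reach 44 and 42 nt, so another processing of that file is not separated from salt in any comparison with 4 h.

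**Figure D1:**
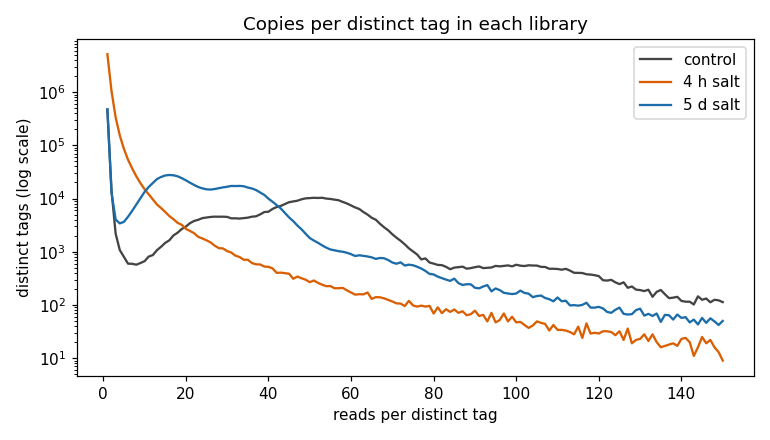
Distinct tags (log axis) against reads per distinct tag for the control, 4 h and 5 d libraries, from 1 to 150 reads. The control line has humps at 27 and 53 reads and the 5 d line at 16 and 33 reads, while the 4 h line has none up to 60 reads.

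Which miRNA families left cleavage ends was asked with 37 conserved families. For each, the reads were counted whose first 9 nt are the exact complement of miRNA nucleotides 2 to 10, and the same word 1 to 8 nt further into the tag served as background. Targets of miR160, miR164 and miR828 left ends at the predicted register in all 3 libraries. The miR160 word, GAGCCAGGC, is found in mRNAs of auxin response factors; it had 3749 reads in the control, 2200 at 4 h and 3066 at 5 d, against at most 65, 25 and 112 reads at any of the 8 shifted registers. The miR164 word, TGCTTCTCC, belongs to mRNAs of NAC transcription factors, which act in organ boundaries and senescence; it had 1831, 812 and 3913 reads in the same order, against at most 224, 80 and 237. The miR828 word, TTGAGCAAG, for MYB transcription factors, had 40.3, 13.0 and 49.8 RPM against at most 11.5, 4.05 and 5.66.

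The words of 3 other families exceeded 3 times their highest shifted register in the 4 h library and not in the control or 5 d libraries. These were miR393, which targets auxin receptor mRNAs of the TIR1 and AFB group, with 1189 reads at 4 h against at most 128; miR394, which targets an F-box mRNA, with 305 against at most 74; and miR827, a family of the phosphate response, with 139 against at most 26. The miR393 register was the highest of 9 in all 3 libraries. It had 700 reads in the control against at most 423, and 763 at 5 d against at most 307. A miR393 signal in those libraries is thus not excluded. miR394 had 118 reads in the control against at most 148, and 98 at 5 d against at most 135. The background for miR394 there was too high to tell a cleavage signal of that size. The factor of 3 was set after the counts had been seen. Without it, 13 of 36 distinct words in the control, 18 at 4 h and 13 at 5 d were highest at the predicted register. If all 9 registers were alike in base content, chance would give 4 of 36. T was the first base of 35.4% of distinct control tags and G of 13.6%, and bases further in were not counted. The excess over 4 is thus not shown to come from cleavage.

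**Figure D2:**
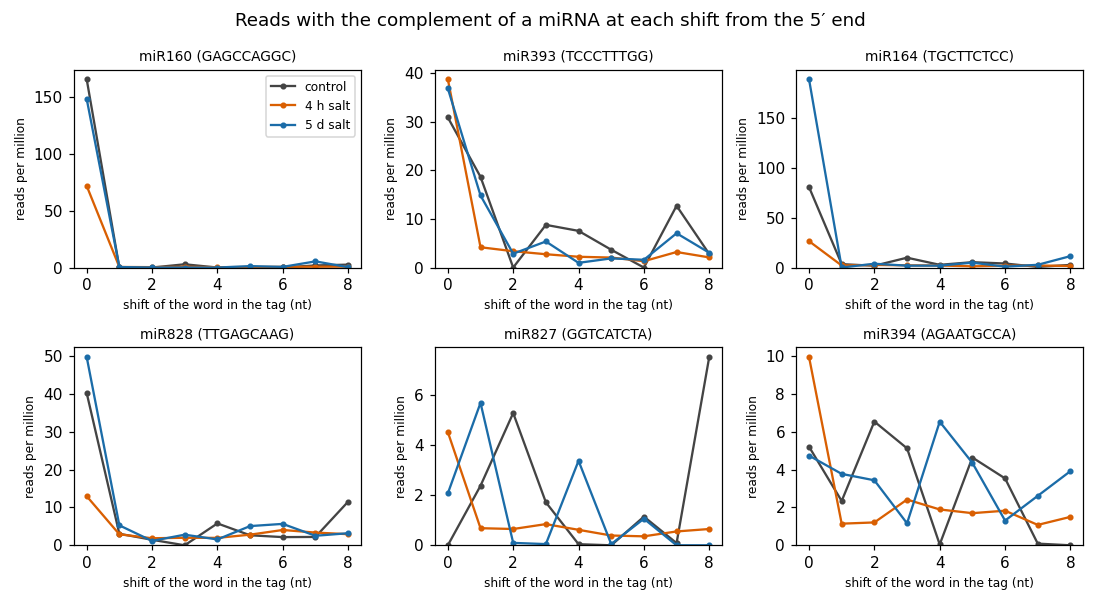
RPM (linear axis) against the shift of the word within the tag, where 0 is the predicted cleavage register, for 6 families in the control, 4 h and 5 d libraries. For miR160, miR164 and miR828 the highest point of each line is at shift 0; for miR393, miR394 and miR827 the 4 h line alone exceeds 3 times its highest shifted point.

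All 37 families together had 256 distinct ends at the register in the control, 1413 at 4 h and 321 at 5 d. The shifted registers had means of 136.4, 1196 and 195.5 in the same order. Such a mean is most of the count in every library, and its part is largest at 4 h. Most single ends in each of the 3 libraries are thus at the level of background. In reads, the register held 574.0 RPM in the control, 280.8 at 4 h and 640.0 at 5 d, which is 3.53, 3.63 and 3.75 times the shifted mean of the same library. The 3 libraries shared 46 of the 1791 ends seen in any of them. The control and 4 h libraries shared 81 ends, the control and 5 d libraries 68, and the 4 h and 5 d libraries 96; the 4 h library had 1282 of its ends to itself. At a minimum of 5 reads, 30 ends of 296 were shared by all 3.

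The first comparison set 4 h of salt against the control. Reads at the miR160 register were 71.8 RPM at 4 h (68.8 to 74.8) and 165.5 in the control (160.2 to 170.9), a ratio of 0.434 (0.411 to 0.457). With the 2 dominant ends left out the ratio was 0.887 (0.841 to 0.935). At the miR164 register the values were 26.5 RPM at 4 h and 80.8 in the control, a ratio of 0.328 (0.301 to 0.356), or 0.670 (0.616 to 0.729) without the 2 ends. The miR828 register gave 13.0 against 40.3 RPM, a ratio of 0.323 (0.286 to 0.363), or 0.660 (0.585 to 0.743). Reads at the miR393 register were 38.8 RPM at 4 h and 30.9 in the control, a ratio of 1.26 (1.14 to 1.38), or 2.57 (2.34 to 2.82) without the 2 ends, and those of miR394 were 9.95 and 5.21 RPM, a ratio of 1.91 (1.54 to 2.38), or 3.91 (3.15 to 4.87). No background was subtracted in any register ratio. In the control, miR393 and miR394 stayed under 3 times their highest shifted register, so their ratios are not fold changes of cleavage ends alone. miR827 had 139 reads at 4 h and 0 in the control, with a lower bound of the ratio of 27.5 in reads. With reads divided by the modal copy number, and the 2 ends left out, the intervals in molecules included 1 for miR160 (0.698 to 1.14) and miR828 (0.412 to 1.16). They were 0.472 to 0.957 for miR164, 1.52 to 4.91 for miR393 and 1.19 to 36.1 for miR394, with a lower bound of 1.06 for miR827. With the copies per molecule doubled in the control, and each 4 h read still 1 molecule, only the interval of miR393, 1.17 to 6.04, excluded 1 among the 6 families. With 27 control reads as 1 molecule instead of 53, the interval of miR828 was 0.461 to 0.960, and those of the other 5 families lay as before with respect to 1. The 2 miR164 ends with most reads at 5 d had a ratio of 4 h to control of 0.202 (0.178 to 0.228), and the rest of that register one of 0.585 (0.518 to 0.661), with an interval in molecules without the 2 dominant ends of 0.684 to 2.49.

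Among single ends with at least 20 reads over both libraries, 21 of 119 had a whole interval above 2-fold and 85 one below 0.5 at 4 h. Leaving the 2 dominant ends out gave 22 and 74. This split follows the library: of all 375240 ends compared in the same way, whatever their sequence, 8.86% lay above and 88.2% below. With reads divided by the modal copy number of the library, so that 53 control reads count as 1 molecule, 0 ends lay above and 14 below, or 1 and 8 with the 2 dominant ends left out as well, and 4 and 37 with 27 control reads as 1 molecule and the 2 ends left out. The end with the highest bound was TGCTTCTCCGTTCTATCT of the miR164 word, with 197 reads at 4 h and 0 in the control, followed by GGTCATCTAAATTCATTT of miR827 with 123 and 0 and GGCTCAATCACTTGTCTC of miR171, which targets GRAS mRNAs, with 103 and 0. The lowest were TCTTCTGTCTTCTCAATC of miR156, which targets SPL mRNAs, with 1 read at 4 h and 206 in the control, and GACAACGAAATGGGAGAC of miR858 with 0 and 125. The control counts of 206 and 125 are only a few times its modal copy number of 53. The words of miR156, miR169, miR171, miR172, miR397 and miR858 exceeded 3 times their highest shifted register in no library. The control had 198 reads against 197 for miR858, but 793 against 265 for miR156, just under the factor. At 5 d, miR397 had 291 reads against 107. The miR156 and miR172 registers were the highest of 9 in all 3 libraries, so a signal of these words is not excluded. The single ends named for these families, here and below, are still not shown to be cleavage sites.

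Set against random ends of the same abundance, the median log2 ratio of 4 of 11 family lists lay outside the central 95% of 10000 random lists at 4 h, and all 4 were above it; when scaled to tags at all sites there were 3, where auxin and GRAS no longer lay outside and NF-Y did, and with a pseudocount of 5 there were 3, where leaf growth no longer did. The auxin list (miR160, miR167, miR390 and miR393) had a median of -0.77 over 13 ends where random lists had -2.37, at percentile 99.1. The GRAS list (miR171) had -0.34 over 4 ends against -2.66, at percentile 99.7. The list for leaf growth and organ boundaries had -2.20 over 19 ends against -2.51, at percentile 98.2, and the list of other conserved families -1.76 over 14 ends against -2.15, at percentile 99.3. The remaining 7 lists lay inside: phase change at percentile 95.03, MYB regulators at 95.3, NF-Y at 90.5, the small RNA pathway at 96.5, copper and oxidative stress at 68.0, sulfate and phosphate at 77.2, and NBS-LRR immune receptors at 92.5. With the forms tried later, phase change lay outside, at percentile 98.05 over 35 ends. The F-box list had too few ends. All 11 lists were thus at percentile 68.0 or higher in this setting. Scaled to tags at all sites, copper and oxidative stress fell to 24.85, NBS-LRR immune receptors to 32.3 and sulfate and phosphate to 44.6. The other lists then stayed at 65.3 or higher. With a pseudocount of 5, NBS-LRR alone fell, to 32.2, and the others stayed at 70.9 or higher. A shift shared by all lists thus depends on the setting. Of ends at the register, 55.5% were in both libraries, against 42.4% of all ends compared. These shares are not matched on abundance, so they do not explain the percentiles. The auxin and GRAS medians turned positive under another scaling or pseudocount, at 0.23 and 0.11. Of the 36 distinct words, 6 exceeded 3 times their highest shifted register in any library. Those of miR167, miR171, miR390 and all in the list of other conserved families did not. Ends of these words are not shown to be cleavage sites, so the lists describe sequence matches.

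The second comparison set 5 d of salt against the control. Ends at the miR164 register were more numerous at 5 d, with 189.2 RPM (183.3 to 195.2) against 80.8 (77.2 to 84.6), a ratio of 2.34 (2.21 to 2.48) and of 2.33 (2.21 to 2.47) without the 2 dominant ends. In molecules, without the 2 dominant ends, the interval was 1.61 to 3.39. The modal copy number is the higher of 2 humps in the control and the lower at 5 d, so these units may differ. With the lowest hump of each library as 1 molecule the miR164 interval was 1.77 to 3.09, and with the highest 1.57 to 3.47. The register ratio rests on the 2 miR164 ends with most reads at 5 d, singled out after their values were seen, which held 3423 reads at 5 d and 1230 in the control. The rest of the register held 490 and 601 reads, 23.7 and 26.5 RPM, a ratio of 0.893 (0.791 to 1.01). Of single ends, TGCTTCTCCGATCCAATA had 97.4 RPM at 5 d and 28.2 in the control, TGCTTCTCCGATCCGATA 68.1 and 26.1, and TGCTTCTCCAATCCCGTC 10.2 and 23.1. Reads at the miR160 register were 148.2 and 165.5 RPM, a ratio of 0.896 (0.854 to 0.940), and those at the miR828 register 49.8 and 40.3, a ratio of 1.24 (1.13 to 1.35). In molecules the intervals of both included 1, at 0.675 to 1.19 and 0.718 to 2.26. The registers of miR393 and miR394 had ratios of 1.19 (1.08 to 1.32) and 0.910 (0.689 to 1.20), and intervals in molecules of 0.649 to 2.45 and 0.177 to 10.0. Neither exceeded 3 times its highest shifted register in these libraries. miR827 had 43 reads at 5 d, against at most 118 at a shifted register, and 0 in the control; the lower bound of the ratio was 12.2 in reads and 0.136 in molecules.

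Of 170 single ends compared between 5 d and control, 71 had a whole interval above 2-fold and 67 one below 0.5, where 68 ends were absent from the control and 62 from the 5 d library. In molecules, 0 ends lay above and 0 below, or 1 and 0 at the lowest hump of each library without the 2 dominant ends. Of all 692894 ends compared in the same way, 50.9% lay above, 41.0% below, and 10.5% were present in both libraries; for ends at the register that last share was 23.5%. The end with the highest bound was again TGCTTCTCCGTTCTATCT of miR164, with 137 reads at 5 d and 0 in the control. TCCCTTTGGATTGAGAAG of miR393 had 116 and 0, and TCCTTGGCTCTGTTTAAT of miR169, which targets NF-YA mRNAs, had 95 and 0. The miR393 word stayed under 3 times its highest shifted register in both of these libraries, so this end is not shown to be a cleavage site. The lowest were TCAAGATTCTGTGAGAAG of miR172, which targets AP2 mRNAs, with 0 reads at 5 d and 128 in the control, and GACAACGAAATGGGAGAC of miR858 with 0 and 125. None of the 12 family lists lay outside the central 95% of random lists. The nearest was leaf growth and organ boundaries, with a median of 0.30 over 22 ends against -0.76 and a percentile of 96.6. With the forms tried later this list turned to the other side, at -1.35 over 44 ends against -0.28, percentile 5.37.

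**Figure D3:**
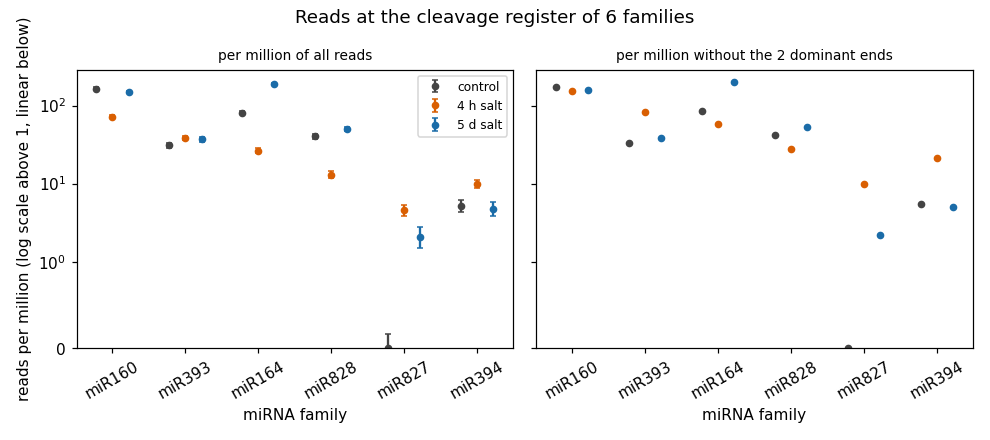
RPM at the cleavage register of 6 families in the control, 4 h and 5 d libraries, over all reads (left, with exact 95% counting intervals as bars) and without the 2 dominant ends (right, no bars); the axis is logarithmic above 1 and linear below. miR164 is highest at 5 d on both sides, while the miR160 values, 71.8 at 4 h and 165.5 in the control on the left, become 155.4 and 175.2 on the right.

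The third comparison set 5 d against 4 h of salt, which differ in how salt was given as well as in time. The miR164 register had 7.14 times the RPM of 4 h at 5 d (6.62 to 7.71), and 3.48 times (3.22 to 3.76) without the 2 dominant ends. miR160 had a ratio of 2.06 (1.95 to 2.18), which became 1.01 (0.952 to 1.06) without them, and miR828 one of 3.83 (3.41 to 4.32), which became 1.87 (1.66 to 2.10). The registers of miR393, miR394 and miR827 had ratios of 0.951 (0.867 to 1.04), 0.476 (0.375 to 0.600) and 0.458 (0.318 to 0.649), and without the 2 ends 0.463 (0.422 to 0.508), 0.232 (0.183 to 0.292) and 0.223 (0.155 to 0.316). In molecules, also without the 2 ends, the intervals were 3.01 to 4.02 for miR164, 0.865 to 1.17 for miR160, 1.40 to 2.42 for miR828, 0.342 to 0.622 for miR393 and 0.0508 to 0.744 for miR827, and the whole interval of miR394 lay below 1. Each 4 h read counts as 1 molecule in these intervals, so they are too narrow if 4 h reads include copies. Outside its 2 leading ends, the miR164 register held 23.7 RPM at 5 d and 15.5 at 4 h, with an interval in molecules of 0.505 to 1.08.

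Of 126 single ends, 85 had a whole interval above 2-fold at 5 d and 15 one below 0.5; in molecules these were 54 and 1, or 38 and 8 with the 2 dominant ends left out as well, and 7 and 2 at the highest hump of each library. Of all 458029 ends compared 87.0% lay above and 6.54% below. CACTCAATGACTCTATAT of miR397, a family that targets laccase mRNAs, had 236 reads at 5 d and 2 at 4 h, and TGCTTCTCCGATCCAATA of miR164 had 2014 and 80. The lowest was GGCTCAATCACCAGCTCT of miR171, with 0 reads at 5 d and 400 at 4 h. It had 98 reads in the control. The medians of 3 of 11 family lists lay below the central 95% of random lists: auxin at 1.29 over 19 ends against 2.04 (percentile 0.0850), GRAS at -2.95 over 3 ends against 2.69 (percentile 0.385), and other conserved families at 0.78 over 12 ends against 1.91 (percentile 0.0100). When scaled to tags at all sites the number was also 3, but auxin lay inside at percentile 3.34 and NF-Y outside at 0.360. As at 4 h, the pseudocount then stands for a far smaller part of a read. All 11 lists lay at percentile 51.0 or lower in this setting. Scaled to tags at all sites, the small RNA pathway rose to 71.4 and copper and oxidative stress to 66.7. The other lists then stayed at 40.8 or lower. With a pseudocount of 5, phase change rose to 74.0 and the others stayed at 44.0 or lower. Here too a shift shared by all lists depends on the setting. Of ends at the register, 55.6% were in both libraries, against 40.8% of all ends compared, shares not matched on abundance. As above, the words of miR171 and of the other conserved families exceeded 3 times their highest shifted register in no library.

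The authors' deposited table of positions, which names no sample, lists 375778 positions on 39314 coding sequences, 19323 with identifiers that start with Cotton_A and 19991 with Cotton_D. Its scaling total of 22653372 equals the total of the control library. It differs by 26.1% from that of 4 h, by 9.51% from that of 5 d and by 69.4% from the sum of the 3. This argues against a table scaled to all 3 libraries, and the position and codon results may be of the control only. The table is not assigned to a library here, since no label does so. Positions lay towards the 3′ end of the coding sequence, with 3.30% in part 1 of 10 equal parts from the 5′ end, 17.4% in part 9 and 16.1% in part 10. By the authors' values, Cotton_A_06457, a coding sequence of 198 nt, had the most reads of all, 1280172. Of these, 650557 were at position 116 and 602192 at position 117. The 2 dominant ends had 652416 and 604287 reads in the control, 8850664 and 7644342 at 4 h, and 603223 and 473866 at 5 d. The counts at the 2 positions were thus closest to those of the control. The files do not pair these identifiers with gene names.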

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

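The test of single-read tags and that of their recurrence were set before their results were seen; the other tests in this part were chosen after the result was seen. In the table of positions, which no comparison between libraries uses, 5′ ends inside coding sequences favoured the second nucleotide of the codon, with 35.7% of 340393 positions (35.5 to 35.8%, exact binomial), against 33.1% at the first and 31.2% at the third. The same reads can be listed under both Cotton_A and Cotton_D, so these positions are not independent: 39.6% of them have the coding length, position and reads of one under the other prefix. With each such combination counted once, the share at the second nucleotide was 35.8% of 262609 (35.6 to 36.0%).

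The most consequential pattern is that most tags of the control and 5 d libraries have either 1 read, 54.6% and 40.3%, or a copy number within 50% of the modal copy number, 34.2% and 29.0%. A count filter before deposit is argued against, since the least filled class between 2 and 19 reads still held 570 tags. Sequencing errors in copied molecules may account for most single-read tags: of 20000 drawn 20-nt tags with 1 read, 93.3% in the control and 73.4% at 5 d lay 1 substitution from a tag with at least 20 reads, against 1.81% at 4 h and 0.0150%, 0.135% and 0.00500% for shuffled sequences in the control, 5 d and 4 h. Few starting molecules are also consistent with the recurrence of control ends in the 4 h library, where 1.43% of single-read ends and 45.9% of ends with at least 20 reads were found, a quotient of 0.0312, although abundant RNA would recur more often in any case. No biological explanation was tested for this pattern.

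The share of 2 neighbouring ends in the 4 h library, 53.8%, is the second pattern. A product formed only in that library is argued against, because the same 2 ends lead the other libraries, at no less than 5.21%. Whether 4 h of salt raised the RNA behind them or the preparation of that library or the processing of its file favoured it cannot be told apart with 1 library.

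The third pattern is at the miR164 register, lower at 4 h and higher at 5 d than in the control. The counting of few molecules as the whole cause of the 5 d difference is argued against, since the ratio in molecules of 2.31 had an interval of 1.61 to 3.39. With the copies per molecule doubled it was 1.42 to 4.19, and 1.01 to 6.85 with the 5% error shared over the 108 intervals of all words and comparisons. Uneven amplification between ends is not covered by these intervals and stays open, and the difference lies in 2 ends, with 165.5 RPM at 5 d and 54.3 in the control. Dilution by the 2 dominant ends lowered the 4 h value by construction, since the ratio was 0.328 with them and 0.670 without. Dilution as the whole cause stays open. Without the 2 ends the interval in molecules was 0.472 to 0.957. That interval widened to 0.423 to 1.18 with the copies doubled in the control and each 4 h read still 1 molecule. An effect of salt on miR164 or its targets stays open and untested, as does any difference between plants, because each condition is 1 library. A difference in plant age or time of day stays open too, since the control has no stated sampling time.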

How the results depend on the processing

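No paired analysis was possible because each group has 1 library. The alternatives on molecules, the 2 dominant ends, words of 10 nt and the forms tried later were chosen after seeing the data. Restriction to degradome categories, transcripts as units and lists of target annotation were not run, since the files give no category, per-library transcript or description. Where no cause is named, the cause was not tested.

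With at least 5 tags, fewer sites remain by construction: 0.410 times the reported number in the control, 0.0899 times at 4 h and 0.502 times at 5 d, with 30 in all 3. Words of 10 nt gave 0.473, 0.354 and 0.452 times the reported number. They leave out the 2 leading miR164 ends, and with them the higher miR164 value at 5 d. Adding the forms tried later gave 1.55 times in the control and 1.63 times at 4 h. Merging within 1 nt gave 96 shared sites.

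For 4 h against control, the numbers of ends above 2-fold were 36 at a minimum of 5 tags, 10 at 50 tags, 40 with tags within 1 nt, 0 in molecules, 1 in molecules without the 2 dominant ends, 4 with the lowest and 1 with the highest hump of each library as 1 molecule, and 34 with the later forms; those below 0.5 were 136 within 1 nt, 14 in molecules, 8 in molecules without the 2 ends, 37 at the lowest and 8 at the highest hump, and 135 with the later forms. For 5 d against control, those above were 121 at 5 tags, 10 at 50 tags, 0 in molecules with or without the 2 ends, 1 at the lowest and 0 at the highest hump, and 108 with the later forms; those below were 42 at 50 tags, 0 in molecules with or without the 2 ends, 0 at the lowest and 0 at the highest hump, and 110 with the later forms. For 5 d against 4 h, those above were 21 at 50 tags, 137 within 1 nt, 54 in molecules, 38 in molecules without the 2 ends, 38 at the lowest and 7 at the highest hump; those below were 27 at 5 tags, 9 at 50 tags, 35 within 1 nt, 1 in molecules, 8 in molecules without the 2 ends, 8 at the lowest and 2 at the highest hump, and 26 with the later forms. Other denominators kept each of these counts within 1.5 times.

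Between 5 d and control, 1 family list lay outside the random lists when scaled to tags at all sites and 1 with a pseudocount of 5. These were leaf growth and phase change in turn. With the forms tried later, leaf growth moved from percentile 96.6 to 5.37 and stayed inside. At 4 h the auxin median became 0.23 when scaled to tags at all sites, and it and GRAS then lay inside the random lists while NF-Y lay outside. For 5 d against 4 h, auxin likewise lay inside and NF-Y outside under that scaling. The same scaling makes the pseudocount a far smaller part of a read, so these moves are not shown to come from the denominator. At 4 h, the GRAS median became 0.11 with a pseudocount of 5.

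Over distinct tags, the share of 20 and 21 nt was 98.7% in the control, 99.1% at 4 h and 96.3% at 5 d, and the share ending in 8 A was 0.192%, 0.191% and 1.39%. The modal copy number of tags with at least 5 reads, 53 in the control and 16 at 5 d, limits what single ends with few reads can show.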

Other observations

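Among the 23 word forms tried after the first search, 3 exceeded 3 times their highest shifted register in at least 1 library, and the other 20 did not. The miR172 form TCAGGATTC, for AP2 mRNAs, had 1738 reads in the control, 2166 at 4 h and 1008 at 5 d, against at most 119, 86 and 151 at shifted registers. The miR167 form GGCAGCTTG, for auxin response factor mRNAs, had 18.4, 17.5 and 36.5 RPM against at most 3.66, 2.90 and 7.15. The miR396 form AGCCTGTGG, for growth-regulating factor mRNAs, had 468 reads at 4 h against at most 56, with 192 in the control and 93 at 5 d against at most 105 and 83. The miR159 form TCATTCCAA, for MYB mRNAs, had 692 reads at 4 h against at most 242, under 3 times. Across the 23 forms, the predicted register was the highest of 9 for 5 in the control, 6 at 4 h and 4 at 5 d. Chance would give 2.56 if all registers were alike in base content, which was not tested.

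The words for trans-acting siRNAs that target auxin response factors stayed under 3 times their highest shifted register. AGGTCAAGA had 256, 214 and 77 reads in the control, 4 h and 5 d libraries, against at most 250, 133 and 231 at shifted registers, and AGGTCAAGG had 4.55, 2.81 and 8.31 RPM against at most 5.12, 2.94 and 5.08. The words of miR168, for AGO1, and miR162, for DCL1, had 0 and 1 reads in the control against at most 70 and 137 at shifted registers, 52 and 31 at 4 h against 76 and 73, and 18 and 58 at 5 d against 77 and 80.

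Without the 2 dominant ends, reads at the miR160 register were 175.2 RPM in the control, 155.4 at 4 h and 156.4 at 5 d. In the same unit miR164 had 85.6, 57.4 and 199.6 and miR828 had 42.6, 28.1 and 52.5.

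In the table of positions, 63 of 15812 coding sequences with at least 5 positions, 0.398%, had 50% or more of their reads at a single position, by the authors' values.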
